A study of Homo sapiens with 12 samples.

How the data were processed

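Guide RNA abundances were measured in THP-1 cells of 1 clone that carried dCas9-BFP-KRAB, a reporter of the cyclic dinucleotide response and a genome-wide CRISPR interference library. Per the labels' protocols, cells were stimulated for 20 h, with 2 µg/ml of 2'3'-RR S2 CDA in the RR screen and 15 µg/ml of 2'3'-cGAMP in the cGAMP screen, and sorted into reporter-low and reporter-high cells, and unsorted cells were kept as background. Sequencing aimed at 2000 reads per guide for unsorted cells and 10 reads per cell for sorted ones, at 500-fold library coverage. The 12 libraries form 6 groups of 2, and the 2 replicates are cultures with independent transductions of the same clone. The screens were read on different Illumina HiSeq models, so sequencer, ligand and dose change together.

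Per the submitters' processing notes, the authors demultiplexed reads with bcl2fastq 2.17 and counted guides with MAGeCK 0.5.2, with hg19 as the build. The deposited RR table holds whole-number counts per guide. The deposited cGAMP table is entered as an estimated count (expected count), since its last line is not a whole number; its guide values are whole, and they were tested as counts. The last 2 lines of that table name no guide and hold column totals, so they stayed out, and 6 unnamed value columns beside it, filled for 20 guides with the values of the same guides in the table, were not used. A spreadsheet had damaged 28 gene cells covering 360 guides, and gene names were therefore read from the guide names. The sort field of 4 samples contradicts the sample title; titles were used, and grouping by that field was an alternative.

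Each table names 209070 guides, of which 104621 had a count in any library and 104449 had none. They target 18905 genes, and 1878 of the 3790 non-targeting guides had counts. Of the gene names, 17440 are current symbols, 1321 matched through 1 synonym and 144 did not match; the names of the tables are printed. Guide names numbering 4009 share all 12 counts with another name (summed count of at least 20), and 1783 such sets carry more than 1 gene. Repeats within a gene (147) were counted once, and named genes that share guides, or whose guides lie within 1000 bp of those of another gene, are marked in the text. Positions are hg19 coordinates from guide names; no genome sequence was at hand.

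Library totals ran from 126.2 to 202.9 M counts, with 134.8 to 181.8 M in the RR screen and 126.2 to 202.9 M in the cGAMP screen, and the Gini index lay between 0.339 and 0.361. Guides were tested with the edgeR 4.0.16 quasi-likelihood fit (R 4.3.3, TMM normalization, mean CPM of at least 1). Guide p-values were ranked in each direction and combined per gene by robust rank aggregation (alpha 0.25, exact null), the smaller of both directions was doubled, and Benjamini-Hochberg adjustment was applied over all genes; called means an adjusted p below 0.05. The gene effect is the median over guides of the replicate mean of log2 ((CPM + 1)/(CPM + 1)). Intervals (95%) and a second gene test came from counts summed per gene in edgeR. These intervals cover counting error and the spread of 2 libraries only, as the reads are PCR products without molecular tags. P-values rest on guides and 2 libraries per group.

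The comparisons were reporter-low against reporter-high cells in each screen, each sorted group against unsorted cells, the difference between the screens as an interaction term, and unsorted cGAMP against unsorted RR cells. Guides tested numbered 102148 in the RR and 101631 in the cGAMP low against high comparison. Of 34 gene lists written beforehand (776 entries), means were tested against 100000 random lists of as many genes, with Benjamini-Hochberg adjustment over the lists; list tests on the difference and on unsorted cells were added after the data were seen. Fits and the main alternatives were fixed before the data were examined.

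Named genes were set by rule. For each low against high comparison up to 12 genes per direction were named, those with the smallest p among called genes with the same sign in both replicates, with up to 6 per direction for the difference and up to 5 for the other comparisons. All members of the STING core, the SLC19 and folate carriers and the type I interferon receptor lists were named, and for other lists the members with the smallest p. Some genes that this rule would name are not reported here.

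The pipeline was tested on simulated data with 3 guides of each changed gene altered. At 2-fold change 62 of 67 genes (92.5%) were recovered in the RR screen, 51 of 67 (76.1%) in the cGAMP screen, 36 of 67 (53.7%) in the difference and 64 of 67 (95.5%) in unsorted cells. At 1.5-fold change the shares were 37.3%, 29.9%, 7.5% and 58.2%. False calls numbered 2, 1, 3 and 6. Simulated guides of like abundance had the same spread, and no deviation was shared by libraries of 1 transduction. In the real data false calls can therefore be more frequent and recovery lower. All simulated libraries of a fit shared the same mean per guide, and only genes with 5 guides were altered. The simulation thus held no guides lost from cGAMP cells alone, and the shares can be too high for genes with such guides. Sets of 5 non-targeting guides (100 draws) were called 0.05 times per draw in the RR screen, 0.09 times in the cGAMP screen and 0.02 times in the difference. Pairing by replicate number was checked through the correlation of deviations from the group mean, which was 0.104 to 0.131 within the RR screen, 0.264 to 0.473 within the cGAMP screen and 0.09 to 0.152 between screens. The main analysis used no block, and a replicate block was tried as an alternative.

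Alternatives tried were DESeq2 1.42.0 size factors and its Wald test, scaling to non-targeting guides, no count filter, a mean CPM of at least 3, a replicate block, the spread of all libraries of a screen, the sort field, repeated guide names kept, an alpha of 0.05 or 1, guides ranked by log2 fold, counts summed per gene, genes split by transcription start site, and leaving out each library. Other tools were limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.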

Results

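A genome-wide CRISPR interference screen was run in THP-1 cells, a human monocytic leukaemia line, to find genes whose knockdown changed the response to cyclic dinucleotides, the small ligands of the innate immune sensor STING. Cells of a single clone carried a dCas9-KRAB repressor, a reporter read as tdTomato fluorescence, and a guide RNA library aimed at promoters. They were stimulated for 20 h with 2'3'-RR S2 CDA at 2 µg/ml, a synthetic cyclic di-adenosine analog with sulfur in its phosphate linkages (the RR screen), or with 2'3'-cGAMP at 15 µg/ml, the natural product of the DNA sensor cGAS (the cGAMP screen). Reporter-low cells, reporter-high cells and unsorted cells were each sequenced for their guides in 2 replicates, which gave 12 libraries in 6 groups. All 12 came from stimulated cells, so a change in the response cannot be told apart from a change in reporter output without ligand. The replicates came from independent transductions of cultures of the same clone, and each culture was divided between the screens. Libraries held 126.2 to 202.9 M counts, with a median of 1049 to 1690 counts per guide and 108 to 731 guides at 0. Replicates of a group correlated at r = 0.91 to 0.964 across guides (log2 CPM), and their counts differed by more than sampling noise, with a chi-square of 25.35 to 54.9 per degree of freedom. A gene's effect below is the median over its guides of the log2 ratio of reporter-low to reporter-high cells, so a positive value means that guides against the gene were enriched among cells with a weak reporter.

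IRF3, the transcription factor that acts below STING and the kinase TBK1, was enriched in reporter-low cells in both screens. Its effect was 2.33 in the RR screen (2.47 and 2.16 in the 2 replicates) and 2.99 in the cGAMP screen (3.17 and 2.44), with adjusted p of 2.07e-10 and 5.85e-13. All 5 IRF3 guides went the same way in every replicate, from 1.25 to 3.54, which checks the sort direction, since knockdown itself was not measured. The sort field of 4 libraries contradicts their titles; grouped by that field instead, IRF3 came to -0.13 in both screens and 0 genes were called in either by edgeR with rank aggregation, with 1018 and 971 at an unadjusted p below 0.05. TMEM173, the gene of STING itself (current symbol STING1), had an effect of 0.41 in the cGAMP screen (adjusted p 0.00819) and 0.15 in the RR screen (adjusted p 0.197). These values rested on few guides. The guide at hg19 position 138861835 (guide names give no chromosome) reached 3.53 and 2.82 in the RR replicates and 3.78 and 4.07 in the cGAMP replicates, while the mean ratios of the other 4 TMEM173 guides lay between -0.39 and 0.72. Summed over its guides, TMEM173 passed in the RR screen too, at 0.68 with a 95% interval of 0.51 to 0.84 and adjusted p of 4.99e-10. TBK1 had an effect of 0.30 in the cGAMP screen (adjusted p 0.0182) and 0.35 in the RR screen (adjusted p 0.0902). Summed over its guides, TBK1 came to 0.60 in the cGAMP screen (95% interval 0.38 to 0.82) and 0.25 in the RR screen (0.07 to 0.44). The median edgeR log2 fold of its guides under cGAMP was 0.32. It was 0.45 without reporter-high replicate 2 and 0.53 without reporter-low replicate 2. Ranking guides by fold ended the cGAMP calls of TMEM173 (adjusted p 0.15) and TBK1 (0.26). Without reporter-high replicate 2 their adjusted p were 0.0626 and 0.0824, without reporter-low replicate 1 that of TMEM173 was 0.0581, and without reporter-low replicate 2 that of TBK1 was 0.123. As a list of 3 genes, the STING core shifted by a mean of 0.94 in the RR screen and 1.23 in the cGAMP screen (permutation test, adjusted p 0.0011 and 0.00017). Of its members 1 of 3 was called higher in the RR screen, 3 of 3 adjusted over the list alone, and 3 of 3 in the cGAMP screen either way.

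**Figure D1:**
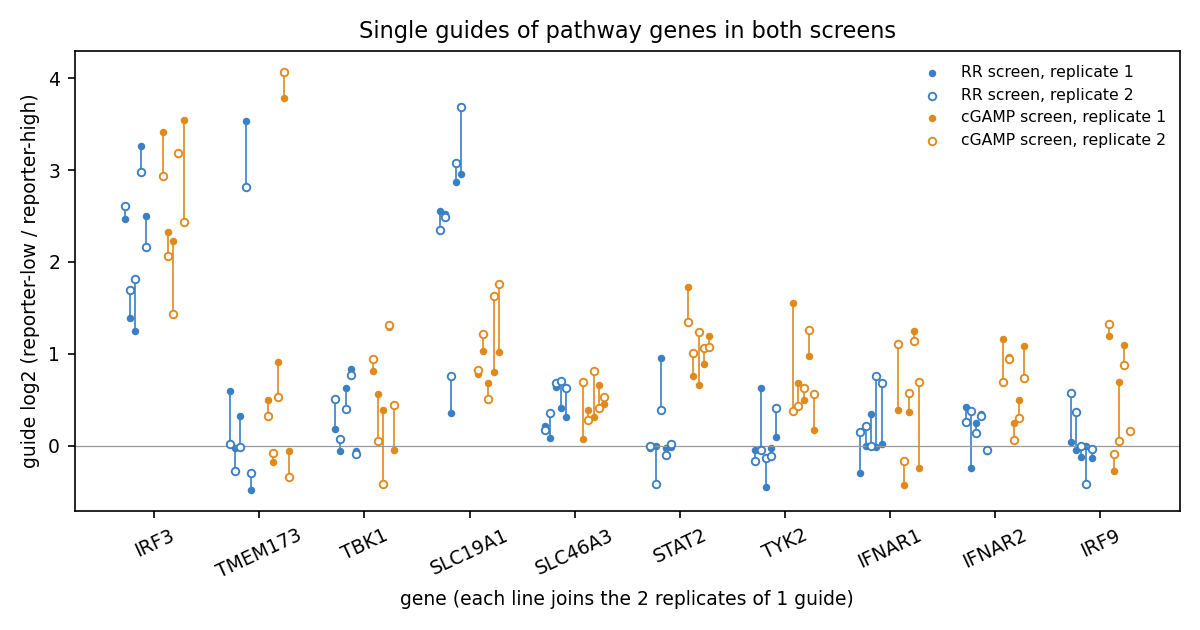
Each line joins the 2 replicate values of 1 guide (filled circle, replicate 1; open circle, replicate 2), as log2 of reporter-low over reporter-high cells, in the RR screen (blue) and the cGAMP screen (orange). All 5 IRF3 guides lie above 1, while a single TMEM173 guide stands apart at 2.82 to 4.07.

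Among 18905 genes tested in the RR screen, 96 were enriched in reporter-low cells and 71 in reporter-high cells. The number depended on the gene test, as counts summed per gene called 311, 185 higher and 126 lower, with 156 of the 167 among them in the same direction. SLC19A1, the reduced folate carrier, had an effect of 2.51 (2.55 and 2.49 in the 2 replicates; adjusted p 3.77e-10), and its 5 guides lay between 0.56 and 3.32. SUPT5H, a transcription elongation factor, and POLR2H, a subunit shared by the nuclear RNA polymerases, had effects of 2.91 and 2.71. Mediator subunits MED19 (1.80) and MED9 (1.23), the Golgi protein ACBD3 (1.67), the pyrimidine synthesis enzyme CAD (1.27) and menin, encoded by MEN1 (1.00), followed. CHAF1B, a histone chaperone subunit, stood at 0.84, and CNOT1 and CNOT3, subunits of a deadenylase complex, at 0.76 and 0.62. In reporter-high cells ARCN1 (-1.12; adjusted p 4.79e-09), COPZ1 (-0.61) and COPG1 (-0.33), subunits of the COPI vesicle coat, were enriched, as were the prohibitins PHB (current symbol PHB1; -1.01) and PHB2 (-0.58). INPP5D, an inositol phosphatase of blood cells, had an effect of -0.60, the ubiquitin ligase gene PELI1 -0.66, the ubiquitin-activating enzyme gene UBA1 -0.34, SCAF1 -0.70, SRSF7, a splicing factor, -0.55, and RBM14 -0.44.

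The RR genes from SLC19A1 to RBM14 above had the same sign in both replicates, with adjusted p from 3.77e-10 to 7.22e-05 (edgeR quasi-likelihood test per guide, rank aggregation per gene, Benjamini-Hochberg). For COPG1, COPZ1 and UBA1 the effect is a median over 10 guides at 2 start sites, P1 and P2 in the guide names, that moved unequally. Guides at P1 lay between -1.46 and -0.37 for COPG1, -1.33 and -0.78 for COPZ1 and -1.24 and -0.46 for UBA1, and guides at P2 between -0.28 and 0.14, -0.44 and -0.07, and -0.21 and 0.18. Split by start site, these 3 genes stayed called (adjusted p 1.68e-07, 1.18e-10 and 9.23e-08), and 170 genes were called in the RR screen. All 7 RBM14 guides share their counts with RBM14-RBM4 or RBM4, and guides of MED19 and PHB2 lie near TMX2 and EMG1, so the effects of these neighbours were not separated; no BCL2L12 effect was called beside IRF3 (adjusted p 0.983 and 0.996 in the 2 screens). The calls for CHAF1B and SRSF7 ended without reporter-high replicate 1 (adjusted p 0.0704) and without reporter-low replicate 2 (0.0992), and the RR count then fell to 108 and 104 genes.

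Mediator, the coactivator that links transcription factors to RNA polymerase II, shifted most broadly in the RR screen. Of its 32 genes 17 were called higher and 0 lower, or 22 adjusted over the list alone, with a mean effect of 0.43 (0.47 and 0.40 in the 2 replicates; permutation adjusted p 0.00034); MED30 had 0.91, MED17 0.97 and MED14 0.91. The COPII and COPI vesicle list went the other way, at a mean of -0.18 (adjusted p 0.00034), with 3 of 26 genes higher and 6 lower, the same counts as adjusted over the list alone. Its higher members were SEC13 (0.52), SEC24C (0.63) and SEC23B (0.35) of the COPII coat, which buds from the endoplasmic reticulum. The 6 lower members were COPI subunits, which serve transport from the Golgi, with COPA at -1.45 (guides near NCSTN) and COPB2 at -1.07. SAGA, a histone acetyltransferase complex, shifted by -0.15 (adjusted p 0.0181), with 2 of 14 genes lower (TAF6L, -0.51; KAT2A, -0.32) and 5 adjusted over the list alone. Small positive means passed for SWI/SNF (0.15, adjusted p 0.0149; SMARCC1 higher, 3 of 18 adjusted over the list alone), for MLL and DOT1L (0.10, 0.0387; MEN1 and KMT2A higher, DPY30 lower, and 3 higher and 1 lower of 18 adjusted over the list alone) and for the vacuolar ATPase (0.10, 0.0405; ATP6V1C1 higher, and 4 higher and 1 lower of 16 adjusted over the list alone). Without the member of largest effect, 2 of the 8 lists passed in the RR screen, Mediator and the COPII and COPI list; the STING core then stood at 0.25 (adjusted p 0.0834), SWI/SNF at 0.10 (0.0834), SAGA at -0.12 (0.0726), MLL and DOT1L at 0.05 (0.47) and the vacuolar ATPase at 0.08 (0.131). With replicate 1 alone the vacuolar ATPase (adjusted p 0.358) and MLL and DOT1L (0.689) did not pass, and with replicate 2 alone the vacuolar ATPase (0.0577) and SAGA (0.0532) did not. The median over genes in place of the mean left 3 lists past the threshold in the RR screen, the STING core, Mediator and the COPII and COPI list.

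In the cGAMP screen 120 of 18904 genes were enriched in reporter-low cells and 94 in reporter-high cells. Besides IRF3, those enriched in reporter-low cells included SMARCC1, a core SWI/SNF subunit (2.52; 2.66 and 2.38 in the 2 replicates), and CAD (2.11). CNOT1 (1.52), CNOT3 (1.08) and CNOT4 (0.91), INTS2 of the Integrator complex (1.46), the cap-binding protein NCBP2 (1.41), SLC19A1 (1.13) and the interferon-activated transcription factor STAT2 (0.97) were also higher, as was B3GALNT1, a glycosyltransferase gene (0.63). In reporter-high cells the histone deacetylase HDAC1 was the most enriched by p, at -1.13 (-1.11 and -0.94; adjusted p 6.4e-11). INPP5D (-1.05) and PELI1 (-1.21) were lower here as in the RR screen, together with UBA1 (-0.25). TTI1, a cochaperone of large kinases whose guides lie near RPRD1B, had -2.18, TBC1D15, a Rab GTPase-activating protein, -1.21, DENR, a translation factor, -0.93, and ARL1, a Golgi GTPase, -0.85. USP18, which restrains interferon receptor signalling, stood at -0.74, ARRDC3 at -0.62 and the autophagy receptor gene CALCOCO2 at -0.42. Adjusted p of all of these ran from 5.85e-13 to 6.29e-05 (edgeR quasi-likelihood, rank aggregation, Benjamini-Hochberg), and the sign held in both replicates. Guides at P1 of CALCOCO2 lay between -1.25 and -0.56 and those at P2 between -0.27 and 0.46; for UBA1 these ranges were -1.54 to -0.34 and -0.16 to 0.84. Split by start site both stayed called, among 225 genes. Counts summed per gene called 185 genes in the cGAMP screen, 105 higher and 80 lower, with 152 of the 214 among them in the same direction. Guides ranked by fold called 171 and kept 144 of the 214. Without reporter-low replicate 2 the calls of USP18 (adjusted p 0.113) and ARRDC3 (0.0656) ended and the count fell to 116 genes; without reporter-high replicate 2 it fell to 128.

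Autophagy genes, which supply lysosomal degradation, moved toward reporter-high cells in the cGAMP screen, with a mean of -0.20 (adjusted p 0.00034). Of 22 genes 5 were lower and 0 higher (7 adjusted over the list alone): EPG5 (-0.71), ATG9A (-0.65), GABARAP (-0.64), BECN1 (-0.51) and PIK3C3 (-0.49). Mediator again lay toward reporter-low cells, at 0.36 (adjusted p 0.00017), with 8 of 32 genes higher and 13 adjusted over the list alone, among them MED14 (0.88), MED21 (0.50) and CCNC (0.89). SWI/SNF had a mean of 0.26 (0.00017), with SMARCC1, SMARCE1 (0.58), PBRM1 (0.64) and DPF2 (0.01 over 10 guides) higher, 4 of 18, or 7 adjusted over the list alone. Integrator, which cleaves nascent transcripts, had a mean of 0.35 (0.00017), with INTS2 and INTS5 (1.09) higher, 2 of 14, or 3 adjusted over the list alone. Means above 0 also passed for the proteasome (0.16, adjusted p 0.000453; PSMD4, 1.26, and PSMD11, 0.97, higher, 2 of 31 either way), respiratory complex I (0.10, 0.00187; NDUFA9 higher, and 6 higher and 1 lower of 41 adjusted over the list alone), the mitochondrial ribosome (0.08, 0.0023; 0 of 57 called, 4 higher adjusted over the list alone), the spliceosome (0.10, 0.00513; 0 of 36 called, 2 higher adjusted over the list alone), MLL and DOT1L (0.12, 0.0167; KMT2A higher, 1 of 18 either way) and the vacuolar ATPase (0.10, 0.036; 0 of 16 called either way). SAGA had a mean of -0.12 (0.0224), with TRRAP lower, 1 of 14 either way. Some of these lists had fewer guides tested here than in the RR screen, on average 4.26 against 5.10 per proteasome gene and 4.61 against 5.39 per spliceosome gene. Medians over fewer and scarcer guides are noisier, and the random lists were not matched for this, so the permutation p of such lists can be too small. Without the member of largest effect, MLL and DOT1L (adjusted p 0.121), the vacuolar ATPase (0.1) and SAGA (0.1) did not pass, and the median over genes in place of the mean left SWI/SNF at 0.02 (0.671) and MLL and DOT1L at 0.05 (0.28). With replicate 1 alone the vacuolar ATPase did not pass (adjusted p 0.109), and with replicate 2 alone the vacuolar ATPase (0.356), SAGA (0.396) and MLL and DOT1L (0.0941) did not.

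**Figure D2:**
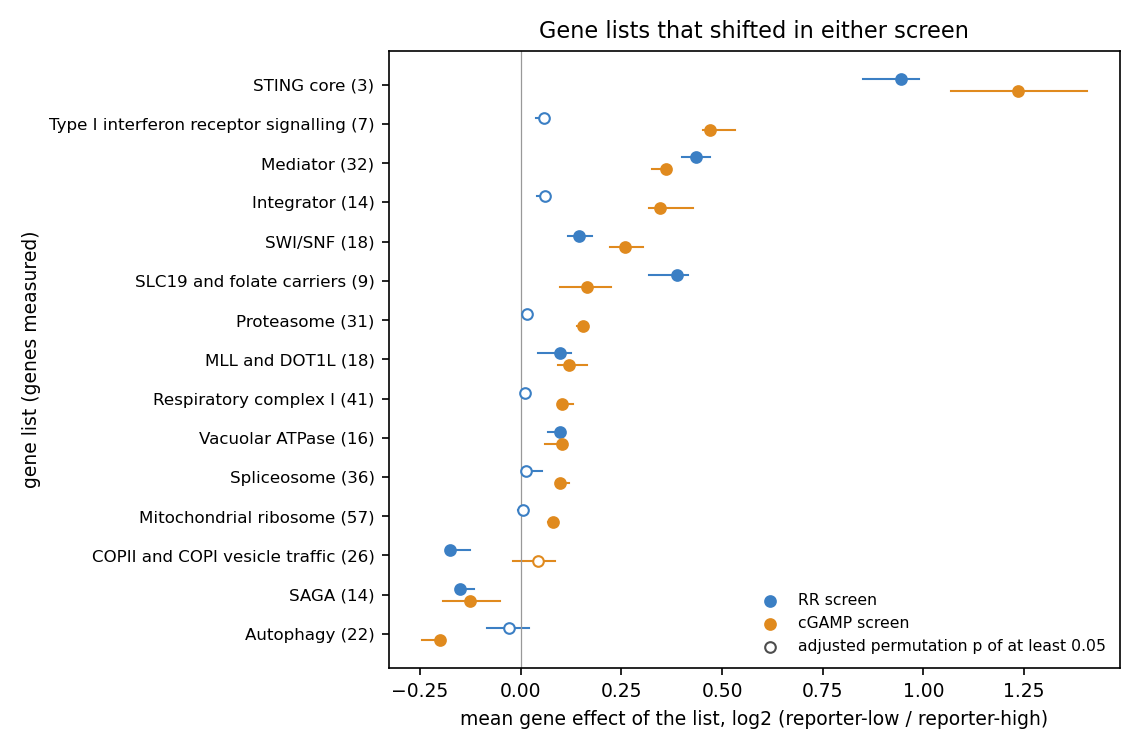
Circles give the mean gene effect of each of the 15 lists past an adjusted permutation p of 0.05 in either screen (log2, reporter-low over reporter-high), filled where that screen passed, and lines span the means of the 2 replicates. The STING core reached 0.94 in the RR screen and 1.23 in the cGAMP screen, and autophagy stood at -0.20 in the cGAMP screen.

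The other lists passed in neither screen in the main analysis, with adjusted p of 0.0711 to 0.977 in the RR screen and 0.0786 to 0.94 in the cGAMP screen (permutation test). They were reported regulators of STING and cGAS, other transporters and channels tied to cyclic dinucleotides, folate and one-carbon metabolism, negative regulators of interferon and nucleic acid sensing, NF-kB signalling, histone acetyltransferases, Polycomb complexes, HDAC corepressors, H3K9 methylation, myeloid transcription factors, N-glycosylation, heparan sulfate and sialic acid synthesis, UFMylation, cullin-RING ligases, mTORC1, the cytosolic ribosome, cholesterol synthesis and other innate sensing pathways. Under alternatives 3 of them passed in the cGAMP screen. By the median over genes these were UFMylation (0.16, adjusted p 0.00939) and histone acetyltransferases (0.09, 0.0471), and heparan sulfate and sialic acid synthesis passed by the mean over guides (-0.08, 0.0413) and with replicate 1 alone (-0.14, 0.0147). Single members were called all the same. The myeloid factor SPI1 was lower in the RR screen (-0.38), TMED2, listed among STING regulators and vesicle genes, was higher in the cGAMP screen (1.18), and FLCN of the mTORC1 list was lower there (-0.53). Markers of T cells, B cells and erythroid cells, 22 genes taken as a negative set, gave 0 calls in either screen by edgeR with rank aggregation; at an unadjusted p below 0.05 there were 3 in the RR screen and 0 in the cGAMP screen.

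SLC19A1 and SLC46A3, a lysosomal solute carrier of the same list of SLC19 and folate carriers, were the 2 of 9 carriers called, in both screens and also adjusted over the list alone. SLC46A3 had an effect of 0.47 in the RR screen (0.31 and 0.63; adjusted p 0.00258) and 0.50 in the cGAMP screen (0.39 and 0.53; adjusted p 0.000994). The relatives SLC19A2 and SLC19A3, the proton-coupled folate transporter SLC46A1, SLC46A2 and the folate receptors FOLR1, FOLR2 and FOLR3 were not called, with effects from -0.11 to 0.26. The list mean was 0.39 in the RR screen (adjusted p 0.00034) and 0.16 in the cGAMP screen (0.0224), and without SLC19A1 it came to 0.12 (0.0834) and 0.04 (0.532). The median over the carriers was 0.06 (0.434) and 0.002 (0.947). With replicate 1 alone the cGAMP mean of the list was 0.10 (adjusted p 0.273). The SLC46A3 calls were less firm than those of SLC19A1: adjusted p rose to 0.145 in the RR screen with guides ranked by fold, to 0.197 without reporter-high replicate 2 and to 0.0958 without reporter-low replicate 2, and to 0.431 and 0.0757 in the cGAMP screen without the same libraries there.

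Genes of the type I interferon receptor pathway separated the screens. In the cGAMP screen 5 of the 7 genes were enriched in reporter-low cells, also adjusted over the list alone: STAT2 (0.97, adjusted p 2.06e-07), the kinase gene TYK2 (0.56, 0.000291), the receptor chains IFNAR2 (0.92, 0.0023) and IFNAR1 (0.48, 0.0358), and IRF9, the partner of STAT2 (0.38, 0.0132). The 2 replicates of IRF9 lay apart, at 0.70 and 0.16. JAK1 (0.02) was not called. In the RR screen 0 of the 7 were called, none had an effect beyond 0.20, and none had an unadjusted p below 0.05 by edgeR with rank aggregation. The list mean was 0.47 in the cGAMP screen (permutation adjusted p 0.000486) and 0.06 in the RR screen (0.416). Tested directly, the difference between the screens was 1.09 for STAT2 (0.91 and 1.15 in the 2 replicates; adjusted p 4.45e-05) and 0.85 for TYK2 (0.95 and 0.53; adjusted p 0.00603), while IRF9 (0.44, adjusted p 0.0693), IFNAR2 (0.59, 0.333) and IFNAR1 (0.30, 0.243) did not pass. The cGAMP calls of IFNAR1, IFNAR2 and IRF9 each ended without reporter-high replicate 2 (adjusted p 0.115, 0.0542 and 0.0597), that of IFNAR1 also without reporter-low replicate 2 (0.792), and those of IFNAR2 and IRF9 without reporter-low replicate 1 (0.215 and 0.121). With guides ranked by fold, IFNAR1 (0.257) and IRF9 (0.163) were not called.

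The 2 ligands differed most clearly at SLC19A1, whose effect was 1.65 lower on the log2 scale in the cGAMP screen (difference -1.65; -1.77 and -1.46 in the 2 replicates; adjusted p 1.3e-08). From counts summed over its guides the difference was -1.47, with a 95% interval of -1.77 to -1.16. In all, the difference passed for 71 genes, 38 with the higher low-to-high ratio under cGAMP and 33 under RR CDA (edgeR interaction term, rank aggregation, Benjamini-Hochberg). The difference was positive, as for STAT2, at TMED2 (1.12), SMARCC1 (0.97), INTS2 (0.97) and CAD (0.81). It was negative, as for SLC19A1, at ACBD3 (-1.96), TBC1D15 (-1.20), TTI1 (-0.76), ARL1 (-0.61) and SCAF1 (-0.46); guides against the last 4 lay further toward reporter-high cells under cGAMP. Counts summed per gene called 52 genes, of which 35 were among the 71, and they ended the calls of SMARCC1 (0.61, adjusted p 0.274), TTI1 (-0.56, 0.765) and SCAF1 (-0.54, 0.284). Other genes did not differ by this test, which does not show that the ligands acted alike on them. With counts summed per gene, the difference was 0.03 for SLC46A3 (95% interval -0.22 to 0.27), 0.21 for TMEM173 (-0.04 to 0.47), 0.35 for TBK1 (0.06 to 0.63) and 0.54 for IRF3 (0.21 to 0.87), with adjusted p of 0.309 or more in that fit. Doses were not matched, at 2 µg/ml against 15 µg/ml, so ligand and dose cannot be told apart. The screens were also sequenced on different instruments. Sets of 5 non-targeting guides were called 0.02 times per draw in the difference, against 1.38 at the rate of genes; 0 calls have a Poisson probability of 0.25 at that rate, too few to exclude an effect of the instrument on all 71 genes. Leaving out reporter-low replicate 2 or reporter-high replicate 2 of the RR screen, or reporter-low replicate 2 of the cGAMP screen, lowered the count to 41, 35 and 47.

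Genes called in both screens mostly shared their direction. Of 18904 genes tested in both, 39 were enriched in reporter-low cells in both screens against 0.6 expected by chance from independent lists (hypergeometric p 1.11e-62), and 16 in reporter-high cells in both against 0.35 (p 9.39e-23). The opposite directions held 0 genes (0.47 expected) and 2 genes (0.45 expected; p 0.0748). Of the 55 shared genes, 41 had the larger absolute effect in the cGAMP screen. Across genes, which are not independent replicates, the effects of the 2 screens correlated with Pearson r = 0.273 and Spearman rho = 0.109 (permutation p 1e-05 for each, the smallest that 100000 permutations can give). These values used effects averaged over the 2 replicates, so they are not to be set against values from single replicates. Single replicates 1 and 2 of the same screen correlated at a Pearson r of 0.247 in the RR screen and 0.288 in the cGAMP screen. The values between screens that follow are also from single replicates. Different-numbered replicates of the 2 screens, which share no transduction, correlated at 0.183 and 0.164, against 0.185 and 0.18 for same-numbered ones. Without the genes called in either screen r was 0.108.

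**Figure D3:**
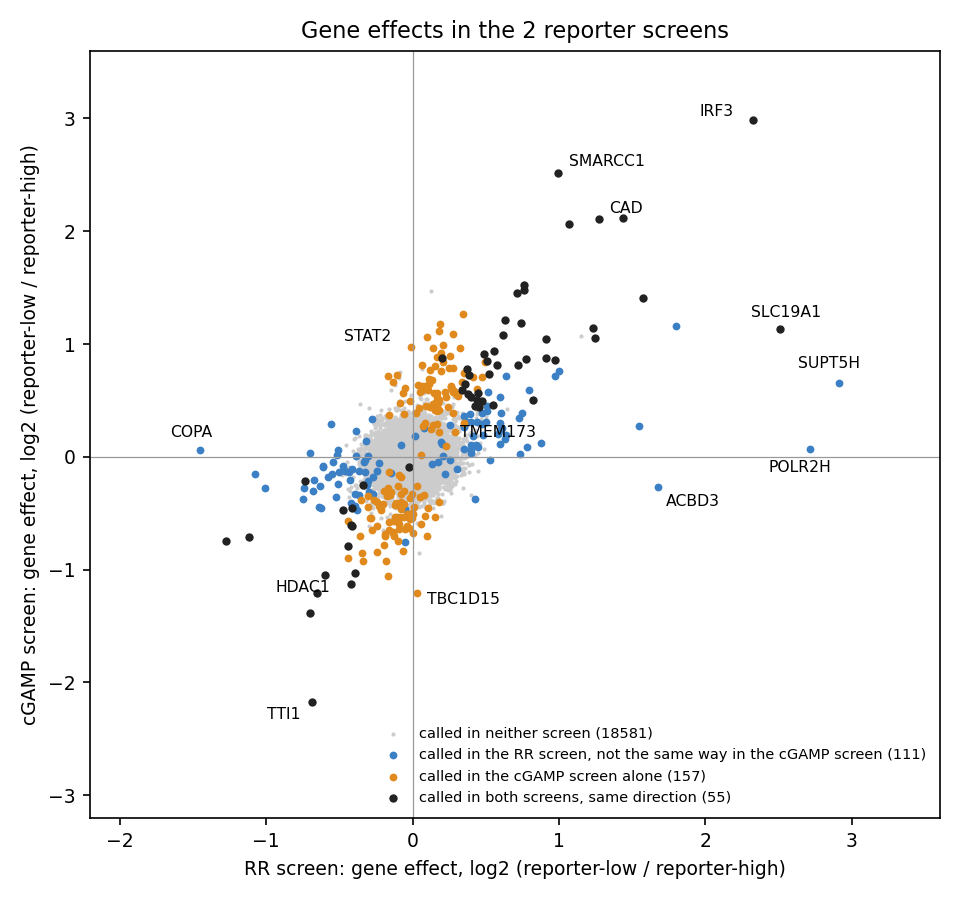
Each point is 1 gene, with its effect in the RR screen (x) and in the cGAMP screen (y), both as log2 of reporter-low over reporter-high cells. The 55 genes called in both with the same direction are black, IRF3 lies highest (2.33 and 2.99), and SLC19A1 lies to the right (2.51 and 1.13).

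Sorted cells set against unsorted cells of the same screen placed SLC19A1 and IRF3 on both sides of the sort. In the RR screen SLC19A1 was 1.26 higher in reporter-low cells than in unsorted cells and -1.33 in reporter-high cells; IRF3 gave 0.82 and -1.15, and SUPT5H 1.39 and -1.52. POLR2H (1.09) and ACBD3 (0.69) were higher in reporter-low cells and MED19 (-1.21) and CAD (-0.58) lower in reporter-high cells. COPA (-1.37), COPB2 (-1.04), ARCN1 (-0.77) and COPG1 (-0.22) were lower in RR reporter-low cells. The nucleolar methyltransferase gene FBL (0.51), TTI1 (0.55), HNRNPDL (0.46) and SPI1 (0.36) were higher in RR reporter-high cells. In the cGAMP screen IRF3 gave 1.21 in reporter-low and -1.70 in reporter-high cells, and SMARCC1 0.95 and -1.49. CAD (1.08) and STAT2 (0.61) were higher in cGAMP reporter-low cells, in which HDAC1 (-0.69), TBC1D15 (-0.70), EPG5 (-0.64), INPP5D (-0.60) and DENR (-0.53) were lower. In cGAMP reporter-high cells CNOT1 (-1.01) and INTS2 (-0.75) were lower, and TTI1 (1.03), ARL1 (0.47), INPP5D (0.42) and HDAC1 (0.41) were higher. The counts of genes called higher and lower were 36 and 19 for RR reporter-low cells, 20 and 45 for RR reporter-high cells, 37 and 32 for cGAMP reporter-low cells, and 34 and 40 for cGAMP reporter-high cells, each against unsorted cells. Adjusted p of the named genes ran from 6.82e-13 to 0.000584 (edgeR quasi-likelihood, rank aggregation, Benjamini-Hochberg). Low and high cells were set against the same unsorted libraries, so these lists are not independent of each other. Counts summed per gene gave 22 and 2 calls for the cGAMP low and high comparisons, and guides ranked by fold gave 33 and 32 for the RR ones. Leaving out 1 library lowered the RR reporter-low count to 27 (unsorted RR replicate 2) and the RR reporter-high count to 29 (RR reporter-high replicate 1). It lowered the cGAMP reporter-low count to 27 (cGAMP reporter-low replicate 2) and the cGAMP reporter-high count to 44 (cGAMP reporter-high replicate 2).

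Before any sort, guides against many genes were scarcer in the cGAMP cells than in the RR cells. Of 18905 genes, 266 were lower and 31 higher in unsorted cGAMP cells (edgeR quasi-likelihood, rank aggregation, Benjamini-Hochberg). The decreases with the smallest p belonged to LSM6, an RNA-processing factor (-2.64; -2.77 and -2.55 in the 2 replicates; adjusted p 4.67e-07), the ribosomal RNA methyltransferase NOP2 (-2.62), the mitotic kinase AURKB (-2.13), CHAF1B (-2.10) and the cardiolipin synthesis enzyme TAMM41 (-1.90). INO80E (0.68, with 2 of its 5 guides shared with HIRIP3), RNF169 (0.50), AMBRA1 (0.41) and HDAC1 (0.41) were higher. Counts summed per gene called 658 genes. Sets of 5 non-targeting guides, 368 per draw, were called 0.1 times per draw.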

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

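The tests of larger effects for all genes, of the sequencer, of guides under the count minimum and of the gene lists on the difference were chosen only after the results were seen. A test of the difference between the screens, cGAMP minus RR, on the low-to-high ratio passed for 71 genes, and these are the results that call for a closer look. The difference was positive for TMED2 (1.12), STAT2 (1.09), SMARCC1 (0.97), INTS2 (0.97), TYK2 (0.85), SRSF7 (0.85), CAD (0.81), NOP2 (0.57), B3GALNT1 (0.53) and NCBP2 (0.26). It was negative for POLR2H (-2.68), SUPT5H (-2.17), ACBD3 (-1.96), SLC19A1 (-1.65), TBC1D15 (-1.20), TTI1 (-0.76), DENR (-0.75), ARL1 (-0.61), HDAC1 (-0.59), SCAF1 (-0.46), TAMM41 (-0.39) and INO80E (-0.18). For TBC1D15, TTI1, DENR, ARL1, HDAC1 and SCAF1 a negative difference means a stronger shift toward reporter-high cells under cGAMP. Counts summed per gene kept 35 of the 71 calls and ended those of SMARCC1 (adjusted p 0.274), TTI1 (0.765), SCAF1 (0.284), NOP2 (0.535) and NCBP2 (0.999).

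Of the gene lists, 12 differed between the screens, 10 with a higher and 2 with a lower mean under cGAMP. The higher ones were type I interferon receptor signalling (0.47), the STING core (0.37), Integrator (0.36), COPII and COPI vesicle traffic (0.19), UFMylation (0.15), SWI/SNF (0.10), the proteasome (0.09), the spliceosome (0.09), the mitochondrial ribosome (0.08) and respiratory complex I (0.07). The lower ones were the SLC19 and folate carriers (-0.21) and autophagy (-0.19). SLC19A1 was the only carrier whose difference passed, and the median of that list was 0.03, with 5 of 9 members above 0. The median of SWI/SNF was -0.03, with 8 of 18 members above 0, so a few members such as SMARCC1 and PBRM1 set its mean. These permutation tests take genes as independent, which genes of 1 pathway are not. Guides of the Integrator, COPII and COPI, UFMylation, proteasome, spliceosome and mitochondrial ribosome lists were also scarcer in unsorted cGAMP cells. The random lists were not matched for such scarce guides, whose ratios are noisier.

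The interferon receptor genes, of which STAT2 and TYK2 passed the test of the difference, were weighed against a general gain of effect size in the cGAMP screen and against the sequencer. Over the 55 genes called in both screens the median ratio of absolute effects was 1.46 (bootstrap 95% interval 1.16 to 1.74). A gain multiplies the RR effect. With 1.74 times the RR effect taken off, the 7 genes kept a mean of 0.50 in the cGAMP screen (counts summed per gene, bootstrap 95% interval 0.20 to 0.79). The list was weighed because it differed. Its mean on the same counts was 0.06 in the RR screen and 0.61 in the cGAMP screen, so a remainder was bound to be left. The bootstrap also takes these genes as independent. The values show only that 1.74 times the measured RR effects falls short of the cGAMP effects. The mean difference of the 7 genes, 0.47, lay above the central 95% of 10000 lists of 7 sets of 5 non-targeting guides (-0.11 to 0.12). This decides little about the sequencer, because the list had already passed on the difference. Low and high libraries of a screen also shared a sequencer model, so an effect on guides whatever their target would largely cancel in their ratio. Ligand, dose and sequencer change together, so they stay open and cannot be told apart. Before the sort 266 genes were already lower in the cGAMP cells, with 0 of these 7 among them, and the labels give no harvest day. Differences between the cultures before the sort therefore stay open too. No biological explanation was tested.

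Of 166 genes called in the RR screen and tested in both, 111 were not called the same way in the cGAMP screen, the COPI genes COPA, COPB1, COPB2, COPG1 and COPZ1 among them. Not being called again does not by itself show a difference. The difference between the screens passed for 0 of 8 COPI genes (edgeR interaction term, rank aggregation). In the cGAMP self-test 76.1% of genes were recovered at 2-fold and 29.9% at 1.5-fold change, so some true effects go uncalled. Loss of guides before the sort was tested first: genes that were also lower in unsorted cGAMP cells were called again in 19 of 67 cases, against 36 of 99 others, an odds ratio of 0.69 (Fisher p 0.316), which leaves that explanation open because the odds fell below 1 without passing the threshold. Guides under the count minimum may account for part of the pattern: genes with fewer guides tested under cGAMP were called again in 10 of 56 cases, against 45 of 110 others, an odds ratio of 0.31 (p 0.00299). Of the 71 genes whose difference passed, 16 had fewer guides tested under cGAMP, against 711 of 18904 genes tested in both. POLR2H had 1 guide left and SUPT5H and NOP2 2 each, so their differences above rest on counts near 0, and CAD, INTS2 and TAMM41 had 4 of 5. Of the 111 genes, 65 had lost no guide to the count minimum, so it cannot account for them. A guide under the minimum only in the cGAMP screen is scarce in those cells, so the 2 explanations overlap and these tests do not separate them. Loss before the sort, tested over all 166 genes, stays open.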

How the results depend on the processing

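The alternative that keeps repeated guide names was chosen only after the data were seen. Leaving out 1 library assumes that the lone library of a group varies like the others. Without 1 library at a time the counts of genes called ran from 104 to 128 in the RR low against high comparison and from 116 to 146 in the cGAMP one. They ran from 27 to 50 for RR low and 29 to 46 for RR high against unsorted cells, from 27 to 63 for cGAMP low and 44 to 63 for cGAMP high, from 35 to 71 for the difference, and from 212 to 309 for unsorted cells. Lists past the threshold numbered 6 with either replicate alone in the RR screen and 11 to 13 in the cGAMP screen, and the correlation between screens was 0.18 to 0.185. Counts summed per gene called 311 genes in the RR screen, 22 for cGAMP low and 2 for cGAMP high against unsorted cells, and 658 in unsorted cells; the cause was not tested. Guides ranked by fold gave 33 for RR low and 32 for RR high against unsorted cells, and the cause was not tested. In the RR screen 3 lists passed by the median over genes and 2 without the member of largest effect; the cause was not tested.

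Grouping by the sort field called 0 genes in both screens, as each group then holds a low and a high library. Effects changed sign in the RR screen for IRF3 (-0.13), SLC19A1 (-0.20), MED9 (-0.04), POLR2H (-0.08), CNOT3 (-0.19), MEN1 (-0.24), CHAF1B (-0.14), ARCN1 (0.15), COPZ1 (0.02), UBA1 (0.04), PHB (0.19), PELI1 (0.04) and SRSF7 (0.09). They did so in the cGAMP screen for IRF3 (-0.13), STAT2 (-0.05), CNOT1 (-0.38), CNOT3 (-0.05), CAD (-0.40), B3GALNT1 (-0.08), INPP5D (0.03), TTI1 (0.18), ARRDC3 (0.09), DENR (0.23), UBA1 (0.07), USP18 (0.10) and TYK2 (-0.21).

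Apart from the sort field and the fits without 1 library, named genes mostly kept their status, called or not called. They did so in 531 of 533 cases in the RR screen and 516 of 520 in the cGAMP screen. Lists kept theirs in 125 of 136 cases in each screen. These cases include genes and lists that were not called in the main analysis and stayed so. Calls of the 8 RR and 14 cGAMP lists past the threshold ended in 11 and 8 of the list cases. Another 3 cGAMP list cases were new calls. Calls that ended without 1 library are named above. A replicate block, which pairs the groups by transduction, gave 164 and 224 genes in the low against high comparisons, 54, 55, 79 and 94 against unsorted cells in the order above, 77 for the difference and 321 in unsorted cells, and in the low against high comparisons it changed no call of a named gene. Against unsorted cells it kept 51 of 65 calls for RR high, and it kept 69 of 71 for the difference. At the depth reached, the self-test found 37.3% of RR genes and 29.9% of cGAMP genes changed 1.5-fold, so smaller effects were often missed.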

Other observations

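The tests of sequencer, PCR or depth and of loss against genes that dividing cells need were chosen only after the result was seen, as were the list tests on unsorted cells and the grouping of COPI genes. Before the sort, guides against 12 lists were scarcer in cGAMP cells than in RR cells and 0 lists were more abundant (permutation test). The proteasome had a mean of -0.45 with 10 of 31 genes lower (16 adjusted over the list alone; PSMC4, -1.96), Mediator -0.41 with 15 of 32 (18; MED19, -2.24), the spliceosome -0.38 with 10 of 36 (24; SNRPB, -1.64), MLL and DOT1L -0.37 with 4 of 18 (5; MEN1, -1.78), COPII and COPI traffic -0.27 with 7 of 26 (9; COPA, -2.02) and the cytosolic ribosome -0.27 with 7 of 53 (20; RPL6, -1.79). Smaller means belonged to UFMylation (-0.25; DDRGK1 and UFL1 lower), Integrator (-0.25; INTS2 and INTS4 lower), the mitochondrial ribosome (-0.13; 7 of 57 lower) and cullin-RING ligases (-0.12; NEDD8 and COPS6 lower). Adjusted p of these ran from 6.8e-05 to 0.0288. The median of UFMylation was -0.07, with 4 of 8 members above 0, and that of MLL and DOT1L was -0.08, with 3 of 18 above 0. A few members thus set most of these 2 means.

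Myeloid transcription factors had a mean of -0.18 (adjusted p 0.00446), with SPI1 (-3.02), a regulator of monocyte identity, and IRF8 (-0.48) lower. The median of that list was -0.02, so SPI1 carried most of the mean. Cholesterol synthesis genes stood at -0.17 (0.00949), with MVD, MBTPS2 and SCAP lower and HMGCS1 (0.30) higher; their median was -0.002, with 10 of 21 above 0. COPI genes, 8 of them, had a mean effect of -0.69 in the RR low against high comparison with 6 lower, and -0.17 in the cGAMP one with 1 lower; the difference passed for 0 of them by edgeR with rank aggregation, with COPZ1, COPA and COPG1 at an unadjusted p below 0.05. Before the sort 5 of the 8 were lower in cGAMP cells, at a mean of -0.67. Of the 5 COPG1 guides at P1, the start site that moved in the RR screen, 2 were tested in the cGAMP low against high comparison (-0.18 and 0.28). All 5 COPZ1 guides at P1 were tested there and lay between -0.22 and 0.04.

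The loss in unsorted cGAMP cells was weighed against technical causes. Sets of 5 non-targeting guides were called 0.1 times per draw, against 5.78 at the rate of genes, which argues against an effect of sequencer, PCR or depth on guides whatever their target. The 177 genes of the cytosolic and mitochondrial ribosome, proteasome and spliceosome lists had a mean of -0.28, below the central 95% of random lists (-0.04 to 0.01). These lists were pooled after each had passed as lower in the same comparison, so this test decides nothing about loss of guides against genes that dividing cells need. More growth before the cGAMP harvest was tested with a bound set beforehand, and the bound against it was met, as the 266 genes lay at -0.03 against non-targeting guides in unsorted RR cells. That bound was void, because the 177 genes lay at 0.01 there, which left no loss measurable in RR cells; the labels give no harvest day, so growth and the ligand itself cannot be told apart.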
